A study of Mus musculus with 6 samples.

How the data were processed

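The libraries were made from the cerebella of individual male mice at day 14, 3 of them Galnt17 knockout and 3 B6C3 wild type, with RNA purified by Trizol, treated with DNase I and prepared with Illumina TruSeq RNA kits, per the labels' protocols. They were sequenced as paired reads of 150 bases on an Illumina HiSeq instrument, per the labels' protocols. The deposited values are whole-number counts of reads per gene, 1 table per library. The counts were made with STAR 2.7.5a against mm10/GRCm38, per the submitters' processing notes, with the Ensembl release 102 annotation, per the file names. Those notes also name edgeR 3.12, but no result of the submitters' own test was used here. The counting options are not given in the sources used here. STAR's tables hold 3 count columns. The column counted without strand was used, because the strand columns split the counts evenly (the first held 49.9% to 50.0%), so reads of overlapping genes on opposite strands cannot be told apart. The 4 lines for unmapped, multimapping, unassigned and ambiguous reads were kept out of library sizes and tests. Unmapped reads made up 6.52% to 17.2% and multimapping reads 3.72% to 4.29% of all reads. No molecular identifiers are named, so reads can be PCR copies of 1 molecule. SEs and intervals of fold changes were derived from the log2 fold change and the F statistic of edgeR's test. They rest on the spread among the animals of a group, moderated by that of other genes (6.36 prior degrees of freedom). An interval made from read counts alone would cover counting error only.

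Groups were taken from the strain label of each sample. The labels share no replicate number between the groups, and replicates were numbered by accession only as names. Gene symbols, biotypes and positions came from GENCODE release 21 (GRCm38, Ensembl release 96), which matched 55227 of the 55487 gene identifiers (99.5%), and 260 were kept without a symbol. Totals of 17111611 to 29840046 counts per library set the precision, and 18237 genes passed edgeR's default filter on low counts (minimum count 10, minimum total 15). The biological coefficient of variation was 8.52%.

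Genes were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, quasi-likelihood F test, two-sided, Benjamini-Hochberg adjusted p below 0.05). Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and adjustment over 29 lists, and again with the correlation estimated and with fry. With the preset correlation 10 lists passed, 4 higher and 6 lower in KO. With an estimated correlation 0 passed, with 3 at an unadjusted p under 0.05, and 4 passed in fry, which tests whether the genes of a list move on balance in 1 direction. The 29 lists were Purkinje cell, mature granule cell, cerebellar interneuron, unipolar brush cell, astrocyte and Bergmann glia, microglia and macrophage, endothelial and mural cell, choroid plexus and ependymal, and brainstem and midbrain markers. The others were granule cell precursor and Hedgehog, proliferation, immature neuron, oligodendrocyte and myelin, oligodendrocyte precursor, meningeal and fibroblast, red blood cell, mucin-type O-glycosylation, Williams-Beuren region, cell adhesion and axon guidance, transmitter receptor, voltage-gated channel, immediate early, endoplasmic reticulum and integrated stress, p53 and apoptosis, interferon-stimulated, reactive glia, cholesterol synthesis, mitochondrially encoded and strain-variable genes. Calls within 10 Mb of Galnt17 and calls per chromosome were compared with Fisher's exact test, two-sided, and neighbouring calls with 10000 random placements. Library measures were compared by exact permutation.

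The grouping, the tests, the lists, the alternatives other than those said to be added later and the rule for named genes were fixed before the data were examined. The rule took Galnt17, then the 12 largest increases and the 12 largest reductions among called protein-coding genes whose groups did not overlap, with a mean of at least 1 CPM in the higher group and a symbol that is no Gm number or Rik name. It then took up to 4 members with the smallest p of each list that passed or held a call, which gave 99 different genes. The result of 1 of these genes is not reported here. Other genes are named where the text says that their values had been seen.

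The steps were tested on simulated data, with counts drawn for 18237 genes from the means and sizes of these libraries and 200 genes changed. The changed genes were taken from those with a mean of at least 1 CPM, and each gene had the same dispersion in both groups. In the data the WT libraries varied more than the KO libraries (median SD of log2 CPM 0.10 against 0.05). The rates below therefore hold for the simulated setting and may differ in the data. For the comparison of KO against WT, edgeR recovered 70% of genes changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 14 false calls among 18037 unchanged genes. Of 3 lists moved in the simulation camera called 3 with the preset and 2 with the estimated correlation, and it called 0 of 26 unmoved lists. The simulated genes were drawn independently, so this cannot show how the preset correlation performs on lists whose genes vary together. In the data the estimated correlation was 0.44 for the choroid plexus, 0.49 for the proliferation and 0.003 for the oligodendrocyte and myelin list.

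Alternatives tried were other scalings (RLE, upper quartile), other tests (DESeq2 1.42.0, edgeR's exact test, limma-voom, robust dispersion, a test against a fold of 1.2), no filter or a filter of 1 CPM in 3 libraries, each strand column, and leaving out each library, gene groups or the region of Galnt17. Windows of 5 and 20 Mb and thresholds of 0.01 and 0.1 were tried for positions. Pseudogenes were matched to protein-coding transcripts with minimap2 2.31 at an identity of at least 0.9 over at least 0.5 of their length. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots. The raw reads and isoforms were not analysed here.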

Results

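RNA was sequenced from the cerebella of 14-day-old male mice, 3 homozygous Galnt17 knockouts (KO) and 3 wild types (WT) of the B6C3 stock, a hybrid of C57BL/6J and C3H/He. Galnt17, formerly Wbscr17, encodes a member of the polypeptide N-acetylgalactosaminyltransferase family, whose enzymes start mucin-type O-glycosylation. Per the labels, mice homozygous for this allele were not born alive on C57BL/6, and live homozygotes came from breeding to B6C3 animals. Each library came from 1 animal. Reads counted in genes totalled 29840046, 23076696 and 20049223 in KO replicates 1, 2 and 3, and 24120704, 17111611 and 20947169 in WT replicates 1, 2 and 3. The design gives 1 comparison, which asks how the cerebellar transcriptome of the KO differed from that of the WT mice. Levels below are CPM, counts scaled to a common library size, as KO mean ± SD against WT mean ± SD with n = 3 each, and adjusted p values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

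Galnt17 itself, the targeted gene (ENSMUSG00000034040, chromosome 5, 130872082 to 131308497, minus strand, GRCm38), had 72, 80 and 63 counts in the KO libraries and 1119, 729 and 963 counts in the WT libraries. Its level was 2.99 ± 0.526 against 45.3 ± 2.21 CPM, 15.3-fold lower in KO (log2 fold change -3.94, SE 0.12, adjusted p = 6.18e-08). Each KO library lay below each WT library, as the labels give the groups. The genes on either side, chosen for their position, did not pass: Caln1 was at 344 ± 6.2 against 316 ± 8.65 CPM (adjusted p = 0.253) and Auts2 at 70.2 ± 3.76 against 75.2 ± 6.76 CPM (adjusted p = 0.516). The part of the gene removed in this allele is not given in the sources used here, so the remaining counts were not assigned to exons. The annotation places 4 other genes within Galnt17 on the same strand.

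Of 18237 genes tested, 143 were higher and 159 lower in KO. Changes of at least 2-fold made up 47 of the higher and 81 of the lower calls. Protein-coding genes gave 83 higher and 116 lower calls, and pseudogenes 34 and 25. In all 302 called genes the 3 KO values did not overlap the 3 WT values, which was so in 23.7% of all tested genes, where chance gives 10%. The number of calls depended on single animals, with 959 higher and 962 lower genes without WT replicate 1. Without KO replicate 1, 2 or 3 there were 39, 28 and 43 higher and 79, 53 and 82 lower genes, and without WT replicate 2 there were 58 and 79. The WT libraries differed more among themselves than the KO libraries, with a median SD of log2 CPM of 0.10 against 0.05 over 10687 genes above 10 CPM. Across genes, the Spearman correlation of GC content with the deviation of a library from the mean was -0.34 in WT replicate 1 and between -0.07 and 0.18 in the other libraries.

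Several of the largest reductions were in genes of the choroid plexus, the epithelium that secretes cerebrospinal fluid. Sostdc1, a secreted inhibitor of BMP and Wnt signalling, was 8.64-fold lower (1.55 ± 1.28 against 12.7 ± 5.64 CPM, adjusted p = 0.0244) and the water channel gene Aqp1 7.02-fold lower (1.63 ± 0.876 against 11.1 ± 3.53 CPM, adjusted p = 0.00466). The potassium channel subunit gene Kcne2 was 6.18-fold lower (1.18 ± 0.962 against 6.90 ± 1.55 CPM) and the folate receptor gene Folr1 5.18-fold lower (2.04 ± 1.10 against 10.3 ± 3.07 CPM). Mfrp, Tmem72 and the tight junction gene Cldn1 were 8.56, 8.03 and 5.62-fold lower. Cacng6, a gamma subunit gene of calcium channels, had 1, 1 and 2 counts in KO and 44, 30 and 44 in WT (0.0586 ± 0.0356 against 1.91 ± 0.203 CPM, log2 fold change -4.99, SE 0.41, adjusted p = 0.000181). The glycine receptor subunit gene Glra1 was at 0.262 ± 0.196 against 1.96 ± 0.987 CPM (adjusted p = 0.0374), Lamp5 at 1.22 ± 0.0771 against 6.78 ± 1.28 CPM (adjusted p = 0.000171) and Calml4 at 0.829 ± 0.326 against 4.74 ± 1.12 CPM (adjusted p = 0.00172). Hmga1b, an intronless copy of the chromatin protein gene Hmga1, was 7.66-fold lower (2.35 ± 0.609 against 18.4 ± 2.67 CPM), while Hmga1, named after its values were seen, rose (59.5 ± 2.56 against 43.5 ± 6.38 CPM, adjusted p = 0.043). Hmga1 lost that call without any 1 of the KO replicates or without WT replicate 2 (highest adjusted p = 0.194). Reads that match both Hmga1 and Hmga1b make these values uncertain, and Mfrp, Glra1, Calml4 and Folr1 overlap other annotated genes. Cacng6, Hmga1b, Aqp1, Calml4 and Lamp5 passed whichever library was left out. Without KO replicate 2 the adjusted p was 0.137 for Sostdc1, 0.0596 for Mfrp, 0.171 for Tmem72, 0.138 for Kcne2, 0.0631 for Cldn1, 0.172 for Glra1 and 0.0606 for Folr1, and without WT replicate 2 it was 0.116 for Sostdc1, 0.121 for Tmem72, 0.112 for Kcne2, 0.136 for Glra1 and 0.0768 for Folr1. Glra1 also missed the threshold without KO replicate 1 (0.0956), KO replicate 3 (0.125) or WT replicate 3 (0.0675). Log2 fold changes moved by over 1.5 times in fold without KO replicate 1, to -2.52 for Sostdc1 (from -3.11), -2.35 for Tmem72 (from -3.01) and -3.37 for Glra1 (from -2.76), and without KO replicate 3, to -3.83 for Sostdc1, -4.04 for Tmem72, -3.77 for Mfrp (from -3.10) and -3.41 for Kcne2 (from -2.63).

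**Figure D1:**
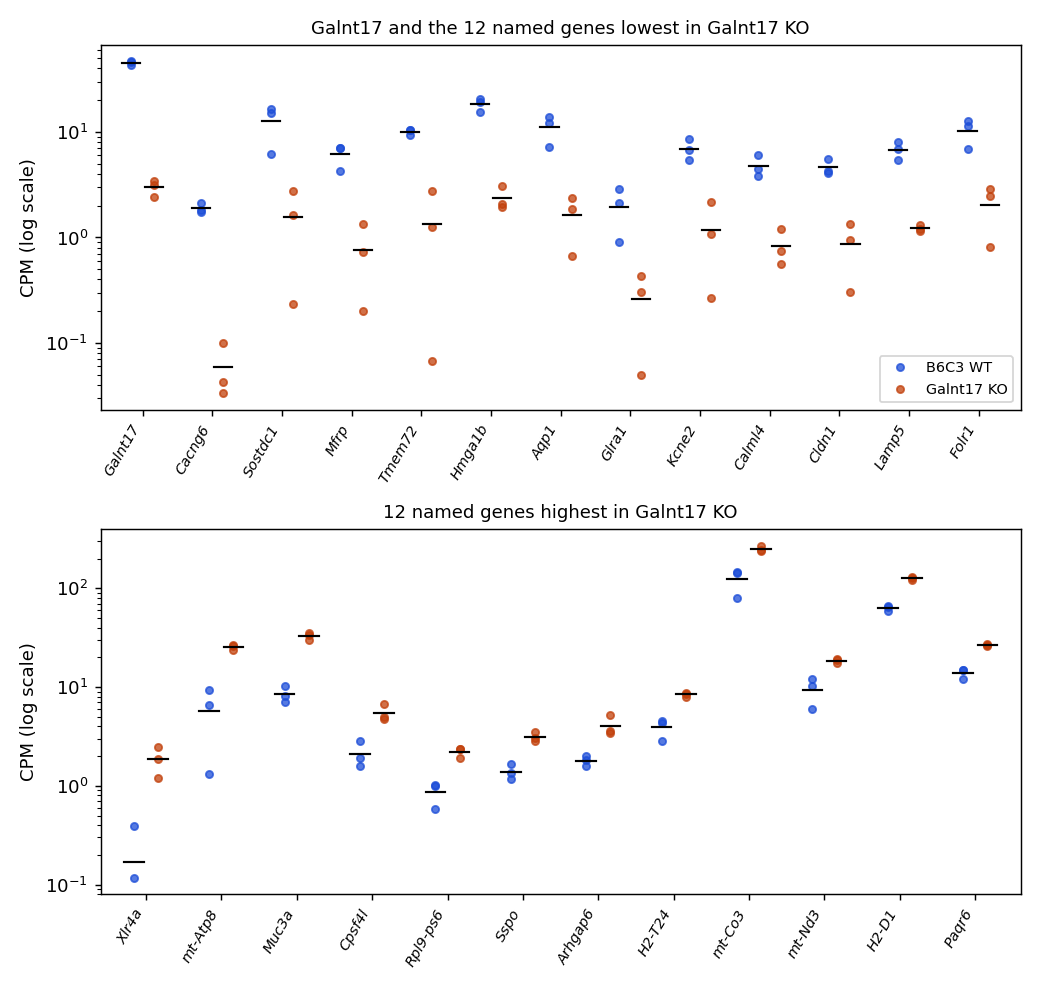
CPM on a log axis for each library (points) and group means (bars) of Galnt17 with the 12 largest named reductions, and of the 12 largest named increases. In every gene shown the 3 KO points lie outside the range of the 3 WT points, and WT replicate 1, with 0 counts of Xlr4a, cannot be drawn there.

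The largest increases were in genes of mixed kinds. Muc3a, a mucin gene (chromosome 5, 137208813 to 137212389), was 3.87-fold higher (33.1 ± 2.72 against 8.47 ± 1.67 CPM, adjusted p = 2.96e-05). Among class I histocompatibility genes of chromosome 17, H2-D1 was 1.98-fold higher (126 ± 4.99 against 63.8 ± 3.69 CPM, adjusted p = 1.87e-05) and H2-T24 2.12-fold higher (8.42 ± 0.374 against 3.93 ± 0.923 CPM, adjusted p = 0.0133). Paqr6, a membrane progestin receptor gene, was 1.90-fold higher (26.8 ± 0.388 against 14.0 ± 1.62 CPM, adjusted p = 0.000686). Xlr4a, of the X-linked lymphocyte-regulated family, had 74, 44 and 24 counts in KO and 0, 2 and 8 in WT (adjusted p = 0.0224). Cpsf4l, the ribosomal protein copy Rpl9-ps6, the SCO-spondin gene Sspo and Arhgap6 were 2.56, 2.51, 2.23 and 2.23-fold higher, and mt-Atp8, mt-Co3 and mt-Nd3 are described with the mitochondrial genes. Xlr4a, Rpl9-ps6, Muc3a and the histocompatibility genes have close relatives, H2-T24 overlaps A930015D03Rik, and Arhgap6 overlaps Hccs on the opposite strand, so their counts are uncertain. All libraries were aligned to the same reference genome, and whether strain variants affected the counts of the histocompatibility genes was not tested. Muc3a, H2-D1 and Paqr6 passed whichever library was left out. The other 9 genes lost the call without KO replicate 1 and without KO replicate 2, with highest adjusted p values of 0.12 for Xlr4a, 0.103 for Cpsf4l, 0.172 for Rpl9-ps6, 0.161 for Sspo, 0.124 for Arhgap6 and 0.0847 for H2-T24. All of these but Xlr4a also lost it without KO replicate 3, and all but H2-T24, mt-Co3 and mt-Nd3 without WT replicate 2 (0.113 for Xlr4a). The log2 fold change of Xlr4a was 3.49, against 2.81 without WT replicate 1 and 5.13 without WT replicate 3.

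In the list of choroid plexus and ependymal markers, the genes that fell are known from the choroid plexus. Of 20 measured members, 9 fell, 0 rose and 11 did not pass, with 14 lower when adjusted over the list alone, and the median log2 fold change was -1.42. The 9 were Sostdc1, Aqp1, Kcne2, Folr1, the autotaxin gene Enpp2 (252 ± 54.1 against 601 ± 179 CPM, adjusted p = 0.0139), the bicarbonate transporter gene Slc4a5 (3.12 ± 1.70 against 11.9 ± 2.64 CPM, adjusted p = 0.0208) and, named after their values were seen, Kl, F5 and Kcnj13. Of genes of motile cilia, named after their values were seen, Foxj1 (8.56 ± 1.04 against 9.70 ± 2.37 CPM, adjusted p = 0.629), Ccdc153, Tmem212 and Dynlrb2 (adjusted p = 0.908, 0.347 and 0.453) did not pass. Rsph1 and Cfap126 (adjusted p = 0.106 and 0.106) passed when adjusted over the list alone and in edgeR's exact test (adjusted p = 0.0309 and 0.0222), but in neither DESeq2 nor limma-voom. Nor did 4 members that are not ciliary genes, Otx2, Slc13a4, Clic6 and Prlr (adjusted p = 0.724, 0.387, 0.0652 and 0.0768), named after their values were seen. Otx2 was at 30.1 ± 1.91 against 31.4 ± 2.30 CPM. Clic6 and Prlr passed in DESeq2, in edgeR's exact test and when adjusted over the list alone, but not in limma-voom. Ttr, named after its values were seen, which encodes the thyroid hormone carrier transthyretin, did not pass (adjusted p = 0.154). Its levels were 4.26, 220.1 and 431 CPM in KO replicates 1, 2 and 3 and 1096, 1861 and 1995 CPM in WT replicates 1, 2 and 3. The camera test with a preset correlation gave an adjusted p of 1.11e-09, and an adjusted p of 0.446 with an estimated correlation. Without KO replicate 2 or WT replicate 2 all of these calls but that of Aqp1 were lost. The highest adjusted p values were 0.0833 for Enpp2, 0.111 for Slc4a5, 0.102 for Kl and 0.199 for F5, all without KO replicate 2. That of Kcnj13 was 0.142, without KO replicate 1. Enpp2, F5 and Kcnj13 were also lost without KO replicate 1, Kcnj13 without KO replicate 3 and F5 without WT replicate 3 (its log2 fold change was -1.92, and -2.58 without KO replicate 3), and these 3 genes overlap other annotated genes. With the mean of the list as a covariate, a fit chosen after the data were seen, 2 higher and 14 lower genes were called in all. The covariate itself differs between the groups and can take up part of any difference between them. In that fit the log2 fold change was -0.19 (SE 0.35, against -2.37, SE 0.37) for Folr1, which is itself part of the covariate. Of genes outside the list, it was 0.93 (SE 0.21, against 0.93, SE 0.09) for Paqr6 and 1.48 (SE 0.45, against 1.16, SE 0.22) for Arhgap6. The calls of these 2 genes ended with a larger SE and no smaller fold.

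**Figure D2:**
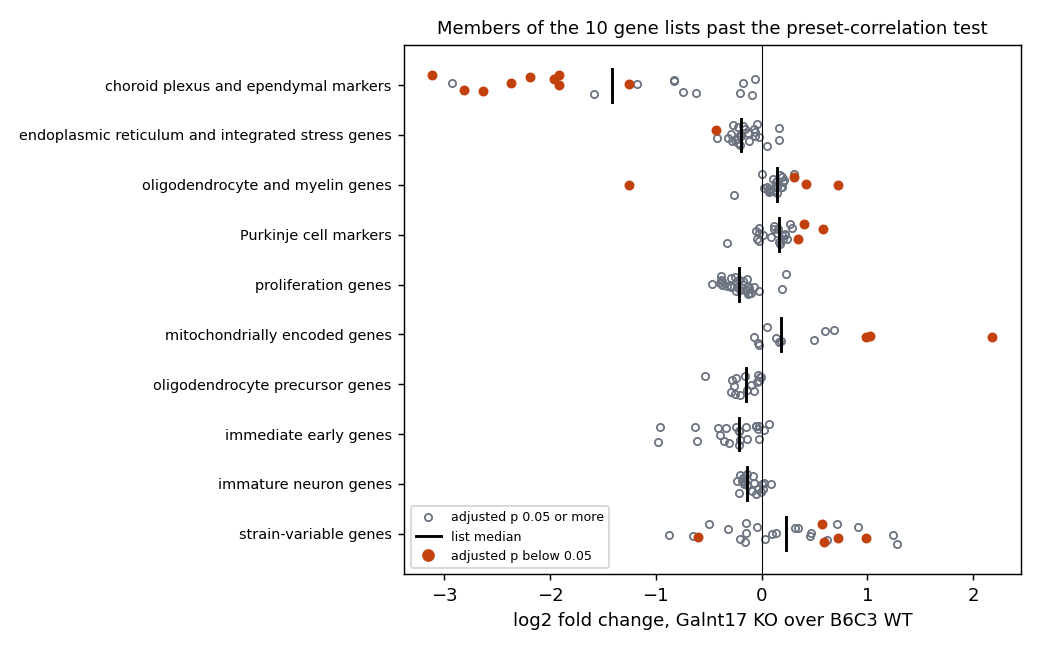
Log2 fold change of KO over WT (horizontal axis) for the measured members of the 10 gene lists past an adjusted p of 0.05 in camera with a preset correlation. Points are genes, filled where the gene itself passed, and bars are list medians, from -1.42 for choroid plexus markers to 0.23 for strain-variable genes.

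Purkinje cell markers were slightly higher. Of 24 measured members, 3 rose, 0 fell and 21 did not pass, with 10 higher when adjusted over the list alone. The G-protein subunit gene Gng13 was at 38.9 ± 2.59 against 26 ± 2.95 CPM (1.5-fold, adjusted p = 0.0123), Pcp2 at 213 ± 9.72 against 168 ± 11.6 CPM (1.27-fold, adjusted p = 0.0261) and Car8, which encodes a carbonic anhydrase-related protein, at 1657 ± 26.5 against 1254 ± 135 CPM (1.32-fold, adjusted p = 0.0371). Homer3 was at 197 ± 3.40 against 169 ± 2.52 CPM and did not pass (adjusted p = 0.0521). Tested with camera, the list had an adjusted p of 7.53e-05, and the adjusted p was 0.28 with an estimated correlation. Gng13, Pcp2 and Car8 lost the call without KO replicate 2 (adjusted p = 0.0924, 0.171 and 0.189) or KO replicate 3, Pcp2 and Car8 without KO replicate 1, and Gng13 and Car8 without WT replicate 2. Gng13 and Pcp2 overlap genes on the opposite strand, Chtf18 and Pet100, and Car8 overlaps 2 other annotated genes.

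Oligodendrocyte and myelin genes were higher too, with 3 of 25 measured members up, 1 down and 21 not passing, and 8 higher and 1 lower when adjusted over the list alone. Ermn, a cytoskeletal gene of myelinating cells, was at 53.8 ± 2.01 against 40.2 ± 0.603 CPM (1.34-fold, adjusted p = 0.00468), the extracellular link protein gene Hapln2 at 23.0 ± 1.35 against 13.9 ± 2.42 CPM (1.65-fold, adjusted p = 0.0162) and the tight junction gene Cldn11 at 355 ± 11 against 287 ± 14.1 CPM (1.24-fold, adjusted p = 0.0321). The member that fell was Enpp2, which the choroid plexus list also holds. In camera the adjusted p was 7.06e-05, and the adjusted p was 0.244 with an estimated correlation. Among 16 oligodendrocyte precursor genes 0 passed in edgeR and limma-voom, 1 was lower in DESeq2 and edgeR's exact test, 5 were lower at an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. Their median log2 fold change was -0.15 (camera adjusted p = 0.00546, and adjusted p = 0.819 with an estimated correlation), with C1ql1 at 15.9 ± 2.35 against 23.1 ± 2.10 CPM and Gpr17 at 119.8 ± 7.25 against 145 ± 20.8 CPM. Without KO replicate 2 the adjusted p was 0.0557 for Ermn, 0.107 for Hapln2 and 0.187 for Cldn11, and the last 2 calls were also lost without KO replicate 1, KO replicate 3 or WT replicate 2. The precursor list lost its call without WT replicate 3 (adjusted p = 0.144), and Ermn overlaps Galnt5 on the opposite strand.

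Genes of dividing cells and young neurons had lower medians without a single call. Of 30 proliferation genes 0 passed in edgeR's quasi-likelihood and exact tests, DESeq2 and limma-voom, also when adjusted over the list alone, and 5 were lower at an unadjusted p under 0.05. Mki67 was at 32.7 ± 5.46 against 42.9 ± 7.94 CPM and Top2a at 30.8 ± 5.54 against 40.2 ± 6.46 CPM, and the median log2 fold change of the list was -0.21 (camera adjusted p = 0.000187, and adjusted p = 0.819 with an estimated correlation). Of 21 immature neuron genes 0 passed in the same tools and when adjusted over the list alone, with 5 lower at an unadjusted p under 0.05. Gap43 was at 229 ± 5.94 against 259 ± 12.9 CPM, and the median was -0.14 (camera adjusted p = 0.018, and adjusted p = 0.819 with an estimated correlation). The immature neuron list lost its call without KO replicate 3 (adjusted p = 0.128) and without WT replicate 2 (adjusted p = 0.324).

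Markers of granule and unipolar brush cells held few calls. Among 22 mature granule cell markers 0 rose and 1 fell, the calretinin gene Calb2, at 339 ± 16.9 against 445 ± 46.4 CPM (adjusted p = 0.0366), with 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.626). Calb2 and the LIM homeobox gene Lmx1a, at 1.2 ± 0.113 against 2.66 ± 0.551 CPM (adjusted p = 0.0421), were the 2 unipolar brush cell markers of 10 that fell, with 2 lower when adjusted over the list alone (camera adjusted p = 0.124, and 0.0195 without KO replicate 3). Of 20 granule cell precursor and Hedgehog genes 0 passed in edgeR and when adjusted over the list alone, 1 was lower in DESeq2 and edgeR's exact test, and 1 was higher and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.505). Calb2 and Lmx1a lost the call without any 1 of the KO replicates or without WT replicate 2, with highest adjusted p values of 0.207 and 0.203, and Lmx1a also without WT replicate 3.

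Endoplasmic reticulum and integrated stress genes were lower. Of 25 measured, 1 fell, 0 rose and 24 did not pass, with 10 lower when adjusted over the list alone. The gene that fell was Pdia4, a protein disulphide isomerase gene, at 40.1 ± 2.68 against 54.1 ± 4.28 CPM (1.35-fold, adjusted p = 0.0215). The chaperone genes Hspa5, Hsp90b1 and Calr were at 276 ± 10.2 against 333 ± 22.8 CPM, 202 ± 2.94 against 241 ± 16.1 CPM and 365 ± 13.5 against 444 ± 41 CPM and did not pass. Tested with camera, the list had an adjusted p of 7.06e-05, and the adjusted p was 0.398 with an estimated correlation. Pdia4 lost the call without KO replicate 2 (adjusted p = 0.139), KO replicate 3 or WT replicate 2. Of 23 measured immediate early genes 0 passed in edgeR's quasi-likelihood and exact tests, DESeq2 and limma-voom, also when adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. Their median was -0.22 (camera adjusted p = 0.0165, and adjusted p = 0.819 with an estimated correlation), with Egr1 at 17.7 ± 4.91 against 26.8 ± 9.23 CPM. That list lost its call without KO replicate 1 (adjusted p = 0.466) and without WT replicate 3 (adjusted p = 0.173).

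Few receptor and interneuron genes passed. Of 43 glutamate, GABA and glycine receptor genes, the AMPA receptor subunit gene Gria4 rose (494 ± 11 against 325 ± 41.3 CPM, 1.52-fold, adjusted p = 0.00558) and Glra1 fell, with 4 higher and 1 lower when adjusted over the list alone. The GABA receptor subunit gene Gabra2 was at 78.6 ± 0.996 against 47.7 ± 16.1 CPM and did not pass (adjusted p = 0.0901). The 39 measured voltage-gated channel genes were tested as a list, with 2 higher and 1 lower when adjusted over the list alone. Of 18 cerebellar interneuron markers, the glycine transporter gene Slc6a5 fell (26.1 ± 1.99 against 39.7 ± 5.82 CPM, adjusted p = 0.0225), with 1 lower when adjusted over the list alone. The camera adjusted p values of the receptor, channel and interneuron lists were 0.628, 0.234 and 0.626 (0.0308 for the channel list on protein-coding genes alone, a fit chosen after the data were seen, and from 0.0308 to 0.819 over its alternatives), and all had a median above 0 and a mean below 0. Of 58 cell adhesion and axon guidance genes 0 passed in edgeR and when adjusted over the list alone, 1 was lower in DESeq2 and edgeR's exact test, and 1 was higher and 7 lower at an unadjusted p under 0.05. The camera adjusted p of that list was 0.0593, and it was 0.0466, 0.00471 and 0.00297 without KO replicate 1, WT replicate 1 and WT replicate 2. Without WT replicate 3 the camera adjusted p was 0.907 and the direction of the list turned. Named after their values were seen, the brainstem and midbrain markers Tph2 (1.07 ± 0.0947 against 3.22 ± 2.94 CPM, adjusted p = 0.167) and Slc17a6 (61.3 ± 4.49 against 80.2 ± 26.3 CPM, adjusted p = 0.307) did not pass. Nor did the glycine receptor gene Glra3 (0.676 ± 0.153 against 1.77 ± 1.84 CPM, adjusted p = 0.292), also named after its values were seen. Tph2, Slc17a6 and Glra3 were highest in WT replicate 3, at 6.61, 109 and 3.89 CPM. Glra1 was also highest there, at 2.87 CPM, and lost its call without that library (adjusted p = 0.0675). Its log2 fold change was then -2.35, SE 0.56, against -2.76, SE 0.55. Glra1 in WT replicates 1 and 2, at 0.911 and 2.11 CPM, still lay above the highest KO library, at 0.436 CPM. With the choroid plexus list as a covariate the log2 fold change of Slc6a5 was -0.19, SE 0.19, against -0.60, SE 0.11 (adjusted p = 0.998). That covariate itself differs between the groups, so the fit cannot tell choroid plexus tissue from genotype as the source. Slc6a5 was at 33.1, 44.1 and 41.9 CPM in WT replicates 1, 2 and 3. Gria4 passed whichever library was left out, while Slc6a5 lost the call without any 1 of the KO replicates or without WT replicate 2 (highest adjusted p = 0.127).

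Glial, vascular and meningeal genes held few calls. Among 24 astrocyte and Bergmann glia markers the septin gene Sept4 rose (540.0 ± 25.5 against 432 ± 31.2 CPM, adjusted p = 0.0463), and among 17 measured reactive glia genes the complement gene C4b rose (7.96 ± 0.504 against 4.84 ± 0.580 CPM, adjusted p = 0.0335), each list with 1 higher when adjusted over the list alone (camera adjusted p = 0.366 and 0.817, the second with a median of -0.01 and a mean of 0.03). Among 19 meningeal and fibroblast genes the insulin-like growth factor binding protein gene Igfbp2 fell (48.0 ± 5.24 against 91.2 ± 21.2 CPM, adjusted p = 0.0133), with 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.497). With the choroid plexus list as a covariate, a fit chosen after the data were seen, the log2 fold change of Igfbp2 was -0.25, SE 0.23, against -0.93, SE 0.15 (adjusted p = 0.998). Since the covariate differs between the groups, this does not separate choroid plexus tissue from genotype. Of 25 microglia and macrophage markers 0 passed in edgeR's quasi-likelihood and exact tests, DESeq2 and limma-voom and when adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.505). Of 19 endothelial and mural cell markers 0 passed in edgeR and when adjusted over the list alone, 1 was lower in DESeq2 and edgeR's exact test and 2 were lower at an unadjusted p under 0.05 (camera adjusted p = 0.505, and 0.0152 without WT replicate 3). Sept4 and C4b lost the call without any 1 of the KO replicates or without WT replicate 2 (highest adjusted p = 0.217 and 0.171), Sept4 also without WT replicate 3 and with a GC trend removed (log2 fold change 0.33, SE 0.07, against 0.32, SE 0.07, adjusted p = 0.053, from 0.000236 to 0.998 over the alternatives), and Igfbp2 without KO replicate 1, KO replicate 3 or WT replicate 2 (highest adjusted p = 0.082).

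Single genes fell in 3 further lists. They were the acetyl-CoA acetyltransferase gene Acat2 among 25 cholesterol synthesis genes (57.1 ± 3.39 against 71.9 ± 2.15 CPM, adjusted p = 0.0238), the pro-apoptotic gene Bcl2l11 among 18 p53 and apoptosis genes (31.6 ± 1.28 against 39.2 ± 1.02 CPM, adjusted p = 0.04) and the alpha-globin gene Hba-a1 among 9 measured red blood cell genes (56.5 ± 5.35 against 81.7 ± 2.43 CPM, adjusted p = 0.00435). Adjusted over the list alone, the counts were 1 lower, then 1 higher and 2 lower, and then 1 lower. The camera adjusted p values were 0.17, 0.505 and 0.505, and that of the cholesterol list was 0.0224 without KO replicate 1 and 0.0275 without WT replicate 1. Of 26 interferon-stimulated genes 0 passed in edgeR, 1 was higher in DESeq2, in edgeR's exact test, at an unadjusted p under 0.05 and when adjusted over the list alone (camera adjusted p = 0.475, and 0.026 without WT replicate 3). Of 5 measured brainstem and midbrain markers 0 passed in edgeR and when adjusted over the list alone, 1 was lower in DESeq2 and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.475). Hba-a1 and Hba-a2, at 17 ± 7.27 against 10.8 ± 1.59 CPM, are near-identical, so both counts are uncertain. Hba-a1 passed whichever library was left out, while Acat2 and Bcl2l11 lost the call without any 1 of the KO replicates or without WT replicate 2 (highest adjusted p = 0.153 and 0.197).

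The enzymes of mucin-type O-glycosylation and the genes around Galnt17 held few or no calls. Of 27 measured O-glycosylation enzymes 0 passed in edgeR and limma-voom, 1 was higher in DESeq2, in edgeR's exact test and when adjusted over the list alone, and 3 were higher and 1 lower at an unadjusted p under 0.05. In camera the adjusted p was 0.628, with a median log2 fold change of 0.01 and a mean of -0.03. Of 37 measured genes of the Williams-Beuren region and its neighbours 0 passed in edgeR's quasi-likelihood and exact tests, DESeq2 and limma-voom, also when adjusted over the list alone, with 2 higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.626). Within 10 Mb of Galnt17, 5 of 297 tested genes were called, against 296 of 17939 elsewhere (odds ratio 1.02, 95% interval 0.326 to 2.44, Fisher's exact test, p = 0.819). Named after their values were seen, these were Muc3a, Trip6 and Gjc3, which rose, and Zkscan1 and 4933404O12Rik, which fell. Within 5 Mb, 0 of 95 genes passed in edgeR, 1 was higher in DESeq2 and in limma-voom, and 1 was higher and 1 lower in edgeR's exact test, with 6 higher and 7 lower at an unadjusted p under 0.05 (Fisher's exact test, p = 0.412). Without KO replicate 2 the adjusted p was 0.228 for Trip6, 0.0606 for Gjc3, 0.11 for Zkscan1 and 0.139 for 4933404O12Rik. Trip6, Zkscan1 and 4933404O12Rik were also lost without KO replicate 1, Trip6 and Zkscan1 without KO replicate 3, Trip6 and 4933404O12Rik without WT replicate 2 and Trip6 without WT replicate 3.

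Part of the mitochondrially encoded genes were higher. Of 13 measured, 3 rose, 0 fell and 10 did not pass, with 3 higher when adjusted over the list alone. The ATP synthase subunit gene mt-Atp8 was at 25.5 ± 1.34 against 5.75 ± 4.05 CPM (4.54-fold, adjusted p = 0.0311), the cytochrome oxidase gene mt-Co3 at 250.03 ± 16.9 against 123 ± 37.6 CPM (2.03-fold, adjusted p = 0.0222) and the complex I gene mt-Nd3 at 18.5 ± 0.846 against 9.45 ± 3.13 CPM (1.98-fold, adjusted p = 0.0382). The more abundant mt-Co1, named after its values were seen, was at 12454 ± 195 against 12705 ± 163 CPM (adjusted p = 0.853). Tested with camera, the list had an adjusted p of 0.00446, and the adjusted p was 0.819 with an estimated correlation. Both mt-Atp8 and mt-Co3 overlap mt-Atp6, and, named after their values were seen, mitochondrial copies on chromosome 1 annotated as Gm28437 (237 ± 11.9 against 97.8 ± 26.4 CPM) and Gm28438 (13.1 ± 1.35 against 3.44 ± 0.752 CPM) rose as well, so these counts are uncertain. With a GC trend removed from each library, a fit chosen after the data were seen, the log2 fold changes were 1.88 for mt-Atp8 (SE 0.46, against 2.18, SE 0.41), 0.93 for mt-Co3 (SE 0.21, against 1.02, SE 0.18) and 0.74 for mt-Nd3 (SE 0.24, against 0.99, SE 0.20). The adjusted p was then 0.0797, 0.0572 and 0.155, where the alternatives ranged from 7.67e-69 to 0.71, 3.11e-51 to 0.864 and 6.45e-14 to 0.939. Leaving out KO replicate 1, 2 or 3 ended these calls too, with highest adjusted p values of 0.127, 0.107 and 0.164, as did leaving out WT replicate 2 for mt-Atp8 (0.118), whose log2 fold change was 2.80 without WT replicate 3.

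Genes known to vary between laboratory strains differed between the groups. Of 26 measured members, 4 rose, 1 fell and 21 did not pass, with 8 higher and 3 lower when adjusted over the list alone. H2-D1, H2-K1, C4b and Wdfy1 rose, with Wdfy1 at 75.2 ± 0.859 against 49.8 ± 2.64 CPM (1.51-fold, adjusted p = 0.00048) and H2-K1, named after its values were seen, at 15.2 ± 0.837 against 10.2 ± 1.18 CPM (adjusted p = 0.0353). The glyoxalase gene Glo1 was 1.52-fold lower (83.1 ± 0.998 against 126 ± 3.20 CPM, log2 fold change -0.60, SE 0.05, adjusted p = 0.00018). In camera the adjusted p was 0.018, and the adjusted p was 0.365 with an estimated correlation. Glo1 and Wdfy1 overlap other annotated genes, such as Dnah8 and Mrpl44 on the opposite strand. Whether strain variants affected how reads of the listed genes aligned to the reference genome was not tested, so a difference in counts need not be one in expression. H2-D1, Wdfy1 and Glo1 passed whichever library was left out, while H2-K1 and C4b lost the call without any 1 of the KO replicates or without WT replicate 2 (highest adjusted p = 0.179 and 0.171).

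Calls were spread unevenly over the genome. Chromosome 17 held 26 calls among 875 tested genes (14 higher and 12 lower, odds ratio 1.90, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0216) and the X chromosome 20 among 636 (10 higher and 10 lower, odds ratio 1.99, adjusted p = 0.0261). On the Y chromosome 5 of 7 were called, all lower (adjusted p = 5.42e-07), and on the mitochondrial genome 4 of 16, all higher (adjusted p = 0.00126). Calls were fewer on chromosomes 4, 10 and 12, with 6 of 1086, 5 of 840 and 3 of 679 (adjusted p = 0.00971, 0.0261 and 0.0261). Of 301 called genes with a position, 34 lay next to another called gene, where 10000 random placements gave a mean of 9.76 (permutation test, p = 0.0001, the smallest they can give). Named after their values were seen, these included Arhgap6, Hccs and Mid1 at the end of the X chromosome, and Gjc3 beside Zkscan1 on chromosome 5. Mid1 lost the call without any 1 of the KO replicates or without WT replicate 2 (highest adjusted p = 0.0993). Some of the neighbours overlap or are copies of each other. With overlapping genes merged into 1 position and without pseudogenes and mitochondrial genes, an alternative chosen after the data were seen, 27 of 234 called positions lay next to another (mean of 7.80 in random placements, permutation test, p = 0.0001, the smallest they can give). Without Y genes as well, 22 of 229 did (mean of 7.57, permutation test, p = 0.0015).

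**Figure D3:**
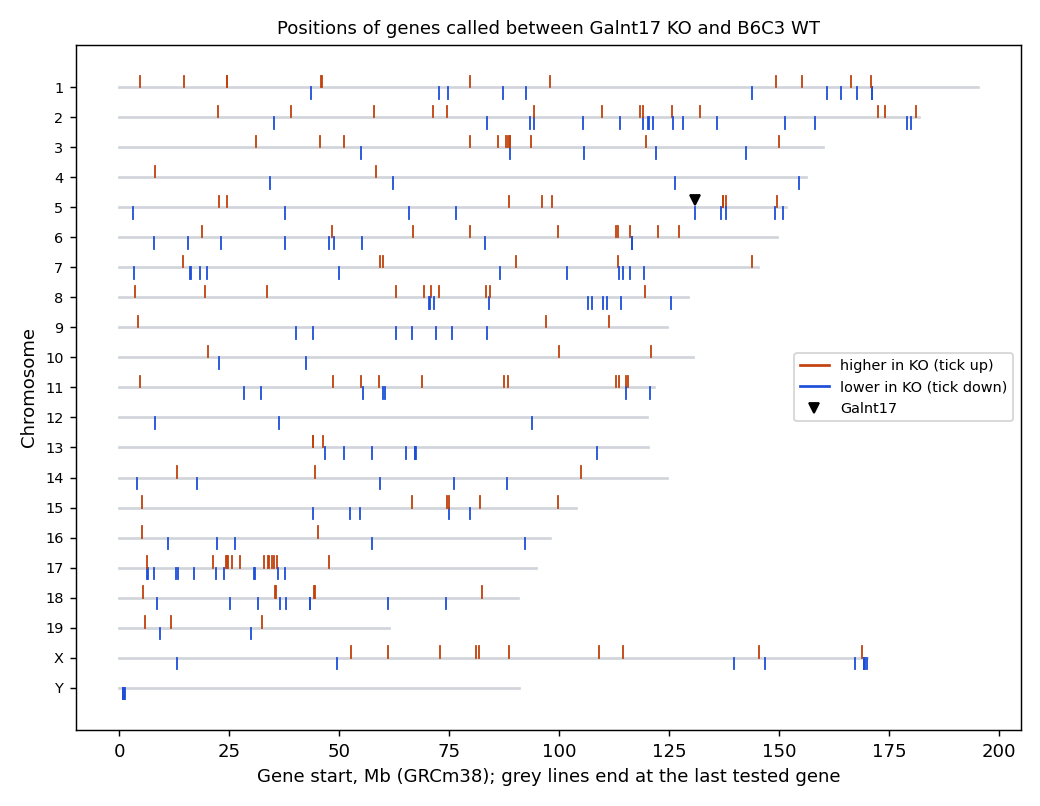
Start positions in Mb (GRCm38) of genes called between KO and WT on chromosomes 1 to 19, X and Y, with ticks up for genes higher in KO and ticks down for genes lower in KO. Grey lines end at the last tested gene, the triangle marks Galnt17, and chromosome 17 carries 26 ticks.

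Libraries of the groups also differed in quality measures. Unmapped reads made up 15.5% ± 1.72 of reads in KO and 8.79% ± 1.96 in WT (SD, n = 3, exact permutation test, p = 0.1, adjusted p = 0.18 over 9 measures), and no comparison of 3 against 3 can give a smaller p than 0.1. Reads assigned to genes made up 68.2% ± 1.29 and 74.8% ± 0.618 (SD, n = 3, exact permutation p = 0.1). Mitochondrial genes took 3.29% ± 0.0705 and 3.11% ± 0.0366 of counts (exact permutation p = 0.1), and haemoglobin genes 0.0208% ± 0.00117 and 0.0220% ± 0.00182 (exact permutation p = 0.4). Whether the groups were collected, prepared and sequenced together is not given in the sources used here, so for genes other than Galnt17 no comparison separated genotype from a batch that coincided with the groups. Strain background can also differ between these same animals. For none of these genes, in any list above, did a comparison separate it from the loss of Galnt17.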

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

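No test in this part was chosen only after the result was seen. Unmapped reads, which enter no gene count, made up 15.5%, 17.2% and 13.8% of reads in KO replicates 1, 2 and 3. They were flagged because all 3 values lie above those of the WT libraries, 6.52%, 9.80% and 10.03%. Unmapped reads were not alone in this. The multimapping, assigned and mitochondrial shares and the share of the 10 most abundant genes did not overlap between the groups either (exact permutation p = 0.1 each).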

How the results depend on the processing

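The fits on protein-coding genes alone, with the choroid plexus list as a covariate and with a GC trend removed were chosen only after the results were seen, as was the merging of overlapping genes. Galnt17 stayed lower in every fit that tested it, with log2 fold changes from -4.12 to -3.64. Counts of higher and lower genes, 143 and 159 in the report, were 290 and 272 with DESeq2 and 495 and 405 with edgeR's exact test, and the cause was not tested. They were 803 and 820 without a filter, where the fitted prior degrees of freedom became infinite (6.36 with the filter), 34 and 80 against a fold of 1.2, a stricter null, and 91 and 94 with fewer, protein-coding genes tested. With the choroid plexus covariate they were 2 and 14. That covariate itself differs between the groups, and the SE of Galnt17 grew from 0.12 to 0.24. There the log2 fold change of Sostdc1, itself part of the covariate, turned to 0.44 (SE 0.46, adjusted p = 0.998, against 0.0244 in the report and from 5.96e-60 to 0.998 over the alternatives). Of genes outside that list, Mfrp went to -0.77, Tmem72 to -0.77, Cldn1 to -0.91, Igfbp2 to -0.25 and Slc6a5 to -0.19, from -3.10, -3.01, -2.49, -0.93 and -0.60, and lost the call. Cacng6 (-4.41, SE 0.91, against -4.99, SE 0.41), Xlr4a (2.92, SE 1.15, against 3.49, SE 0.62) and Wdfy1 (0.54, SE 0.13, against 0.59, SE 0.06) lost it too, each with a larger SE. Leaving out 1 library gave 28 to 959 higher and 53 to 962 lower genes, where 1 animal fewer lowers the power. The cause of the rise without WT replicate 1 was not tested, and the biological coefficient of variation was 6.48% without it against 8.52%. The 46 called genes named by the rule, Galnt17 aside, gave 791 results of the same call, 212 no longer past the threshold and 1 turned. Of the 46, 43 lost the call with the covariate (Sostdc1 included), 33 without KO replicate 2, 27 without WT replicate 2, 24 without KO replicate 1, 24 without KO replicate 3 and 3 without WT replicate 3. The call was also lost by 23 against a fold of 1.2, by 10 with robust dispersion (mt-Atp8, mt-Co3, mt-Nd3, Sostdc1, Tmem72, Kcne2, Folr1, Enpp2, Slc4a5 and Igfbp2), by 7 on the first-strand and 7 on the second-strand column, by 4 with the GC trend removed, by 3 in limma-voom (Sostdc1, Glra1 and Lmx1a), by 3 on protein-coding genes (Calb2, Lmx1a and Bcl2l11) and by 2 in DESeq2 (Tmem72 and mt-Atp8). Called neighbours numbered 56 with DESeq2 (permutation test, p = 0.0061) and 89 at a threshold of 0.1 (p = 0.0001, the smallest placements can give), where more genes were called, against 34. They numbered 27 with overlapping genes merged and without pseudogenes and mitochondrial genes (permutation test, p = 0.0001), and 22 without Y genes as well (p = 0.0015), where fewer positions were called. With an estimated correlation the adjusted p was 0.28 for Purkinje, 0.446 for choroid plexus, 0.398 for endoplasmic reticulum, 0.244 for oligodendrocyte and 0.365 for strain-variable lists, and 0.819 for proliferation, immature neuron, precursor, immediate early and mitochondrial lists. With fry it was 0.096 for choroid plexus, 0.494 for proliferation, 0.514 for immature neuron, 0.431 for precursor, 0.568 for immediate early and 0.423 for mitochondrial lists, and the cause was not tested. It was 0.0592 for immature neurons on protein-coding genes, and 0.0536 for immediate early and 0.052 for strain-variable genes on the second-strand column, for which the cause was not tested. Over omissions of 1 library it ran from 0.00301 to 0.324 for immature neuron, from 0.00224 to 0.144 for precursor and from 2.99e-05 to 0.466 for immediate early lists. The odds ratio near Galnt17 ran from 0 to 1.5 over its alternatives and passed in none of them. Genes removed by a setting have no value there, such as mt-Atp8, mt-Co3 and mt-Nd3 without mitochondrial genes, Muc3a without the region of Galnt17, Glra1 with a filter of 1 CPM and Xlr4a on the second-strand column. No paired analysis was possible because the labels give the groups no shared replicate numbers.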

Other observations

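The tests of an explanation in this part were chosen only after the result was seen, except the count over other splits of the libraries. Genes are also named here after their values were seen. On the Y chromosome, the histone demethylase gene Kdm5d was 1.88-fold lower in KO (56.8 ± 3.42 against 107 ± 9.50 CPM, edgeR adjusted p = 0.000171), the translation factor gene Eif2s3y 1.95-fold lower (98.0 ± 7.27 against 191 ± 34.7 CPM, adjusted p = 0.00197), Uty 1.81-fold lower (37.5 ± 1.87 against 68.0 ± 8.17 CPM, adjusted p = 0.000675) and the RNA helicase gene Ddx3y 1.56-fold lower (84.6 ± 1.45 against 132 ± 11.5 CPM, adjusted p = 0.000763), which overlaps annotated copies. At the distal end of the X chromosome, the haem lyase gene Hccs was 1.82-fold lower (40.2 ± 1.48 against 73.4 ± 1.03 CPM, adjusted p = 1.87e-05), and it overlaps Arhgap6. These 5 genes passed whichever library was left out.

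Several other genes fell by smaller folds. The secretory granule gene Scg5 was at 151 ± 2.61 against 238 ± 5.72 CPM (edgeR adjusted p = 0.000114), the neuronal pentraxin receptor gene Nptxr at 286 ± 3.86 against 437 ± 44.6 CPM (adjusted p = 0.00248), the growth factor gene Hbegf at 46.6 ± 2.21 against 72.4 ± 2.55 CPM (adjusted p = 0.000367) and the proteoglycan gene Spock1 at 145 ± 7.75 against 209 ± 14.6 CPM (adjusted p = 0.00319). The thyroid hormone receptor gene Thrb was at 11.9 ± 0.0718 against 19.9 ± 0.388 CPM (adjusted p = 0.00133). Nptxr and Thrb overlap other annotated genes. The potassium channel gene Kcng4 rose (133 ± 3.26 against 94.0 ± 2.02 CPM, adjusted p = 0.000686). These 6 genes passed whichever library was left out.

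The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 302 genes and the highest of the others 0, and 1 split of the 10, the real one, called as many. Each of the others mixes KO and WT animals, so a group difference of any cause widens its spread and lowers its calls. These splits held 217 to 1436 genes at an unadjusted edgeR p under 0.05, and the real one 3201. Their 0 calls are therefore partly set by the mixing and say little about chance.

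Of 52 called pseudogenes with a protein-coding match, 23 were lower and 29 higher in KO. Lower copies include Gm15772 (3.86 ± 0.517 against 54.5 ± 4.58 CPM), whose match Rpl26 rose (186 ± 6.23 against 115 ± 9.46 CPM). For the lower copies, the median log2 fold change of their matches was 0.21, outside the middle 95% of random sets, -0.11 to -0.01. A change in the copies alone would have kept it inside. Copies that share a match were counted separately, and the random sets were not matched for expression. The median therefore cannot decide the question for the lower copies as a set. Of the 23 lower copies, 14 had a match that was higher, 7 a match called higher and 1 a match called lower. The matches of the 29 higher copies had a median of -0.02, inside that range, so a change in those copies alone stays open. Reads shared between a gene and its copy, for instance through a strain variant that moves reads from 1 to the other, may contribute, and this stays open because the matches of lower and higher copies gave p = 0.0904 (permutation test, two-sided). The log2 fold changes of the copies named here are therefore uncertain.

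Calls lay in blocks and at strain-variable genes, with 34 called genes next to another call against a mean of 9.76 in random placements, and 22 against 7.57 with overlapping genes merged and without pseudogenes, mitochondrial and Y genes. A segment within 10 Mb of Galnt17, carried along with the targeted allele, is argued against as the main source, since 1.66% of the other calls (95% exact binomial interval 0.542 to 3.83) lay there. That window held 297 tested genes, so it could hardly hold most calls, and a small part from such a segment stays open. The 5 calls there started between 136.9 and 138.1 Mb, all on 1 side of Galnt17. Inherited C57BL/6 or C3H segments that differ between the groups may account for some of the blocks, while other neighbours are overlapping genes or copies. The Glo1 ratio of WT over KO of 1.52 (95% interval 1.41 to 1.64) is consistent with 1 C3H copy of a duplicated Glo1 in the WT mice, which predicts 1.5. Strain background and the loss of Galnt17 differ between the same animals, and an effect of the loss itself on these genes stays open and untested.

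Choroid plexus markers were lower in KO, and 10 of the 19 members other than Ttr ordered the 3 KO libraries as Ttr did, where random lists of matched expression gave a mean of 3.45 (permutation over random lists, p = 0.001). The 10 held 8 of the 9 called members, and also Otx2, which did not pass between the groups (edgeR adjusted p = 0.724). The ciliary genes Foxj1, Ccdc153, Tmem212, Rsph1, Cfap126 and Dynlrb2 did not share the order. Neither did the called gene Kcnj13, nor Prlr and Slc13a4. Differing amounts of choroid plexus tissue in the dissected samples may account for the spread among the KO libraries. The shared order shows that these genes vary together. It cannot tell the amount of tissue from a genotype effect that differs between animals. A fixed effect of the genotype on these genes stays open. Ttr differed 101.2-fold between the highest and the lowest KO library and 1.82-fold among the WT libraries, yet each KO library lay below each WT library. A smaller choroid plexus in the mutants was not tested and stays open.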
